A study of Mus musculus with 12 samples.

How the data were processed

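RNA of alveolar macrophages, collected from male C57 Black mice with magnetic beads and an antibody to Siglec-F, was hybridised to Clariom S mouse arrays. There were 12 arrays in 4 groups of 3 biological replicates: intact liver, and 1, 3 and 7 days after resection of 70% of the liver. The deposited values are log2 signals per probe set that the authors made with RMA in the Transcriptome Analysis Console, per the labels, which give no version of either. RMA corrects background, normalizes quantiles over the arrays and summarises the probes of a set. That the scale is log2 was read from the values themselves, and the values were used as deposited.

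The deposited table holds 28846 probe sets. Of these, 6640 control probe sets were left out of the tests and used only to describe the arrays: 1324 exon and 5222 intron controls, 63 ERCC controls and 31 labelling, hybridisation and other controls. The remaining 22206 were tested. The probe annotation supplied with the table gave 19572 of them exactly 1 gene symbol and 2634 none. No genome build is given in the sources used here, so no coordinates are printed. For each array the area under the curve separating exon from intron controls was computed, with the levels of the labelling controls dap, phe, thr and lys and of the hybridisation control bioB. An array below 0.84 in the first measure was called weakly separating and an array above 5 in dap was said to carry the labelling control; both limits were set after the values were seen.

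Each comparison was fitted in limma 3.58.1 under R 4.3.3, with 1 linear model over all 12 arrays, the group as the only term, and empirical Bayes moderation with default settings. The contrasts were each day against intact and the 3 pairs of days, with a moderated F test over the 4 groups. All tests were two-sided, with Benjamini-Hochberg adjustment over the 22206 probe sets of a comparison and a threshold of 0.05. No exact permutation test of 3 against 3 arrays can reach that threshold, so the p-values rest on limma's pooled spread.

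Gene groups were tested with 47 lists of pathway genes and cell type markers. They held 1014 entries, of which 916 were measured, with 1 probe set per gene, the one of highest mean, over 19505 genes. Each list was tested against all other genes with limma's camera at a preset correlation of 0.01, with adjustment over 141 tests (47 lists in 3 comparisons). Camera with an estimated correlation and fry, which asks whether a list moves on balance in one direction, were alternatives. Members were also adjusted over the list alone. A list score is the mean of its members on an array.

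Genes were named by a rule. For each day against intact it took the 10 largest rises and 10 largest falls past the threshold among genes with 1 symbol whose groups did not overlap, which chance gives for 10% of genes with 3 against 3 arrays. Where fewer passed, those with the smallest unadjusted p in that direction filled the places, as values that did not pass. Predicted genes, receptor families for smell, small RNA genes and antigen receptor segments were left out. The rule also took up to 4 members of each list with the smallest p and 17 fixed genes, and 5 genes each way between days.

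The comparisons, lists, naming rule and a first set of alternatives were fixed before the data were examined. That set held other moderation, filters on dim probe sets, quantile normalization or median centring, only the compared groups, a replicate block, array weights, other thresholds, 1 probe set per gene, the mean of a gene's probe sets, each array left out in turn, an estimated correlation and fry. Alternatives that left out weakly separating arrays or arrays with the labelling control, that used this control as a block, or that pooled all resected arrays were added after the data were seen. Of the tests of explanations in the closing section, those by regrouping arrays were laid down beforehand and the others after the results were seen. The regrouping of the pooled arrays rests on a pooling added after the data were seen. For shares of list members the bound of 80% was set after the values per day were known. The margin of 2 binomial standard errors below it was added only after the shares themselves had been seen.

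The procedure was tested on simulated data with the real means and moderated spreads and with genes independent of each other, in which 50 genes were changed at each fold. With day 1 against intact 62, 96, 98 and 100% of genes changed 2, 4, 8 and 16-fold were recovered, with 6 false calls among 184. With day 3 the shares were 52, 96, 100 and 100%, with 8 false calls among 182, and with day 7 they were 48, 98, 98 and 100%, with 7 among 179. The simulated noise of a gene had the same size on every array, whereas the real arrays had weights from 0.19 to 2.32. These shares therefore do not give the power of the real comparisons. Shared intact arrays were simulated 100 times with unchanged groups.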

Results

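Gene expression was measured in alveolar macrophages of male C57 Black mice with an intact liver and at 1, 3 and 7 days after removal of 70% of the liver. The cells were sorted with magnetic beads and an antibody to Siglec-F, a sialic acid-binding lectin that alveolar macrophages and eosinophils carry. There were 4 groups of 3 biological replicates, and each replicate was hybridised to 1 Clariom S mouse array, so 12 arrays entered the comparisons. The log2 values ran from 1.07 to 12.79, with array medians between 3.09 and 3.19. The median of the intron control probe sets, a measure of background, lay between 2.39 and 2.76 and their upper 95% limit between 5.01 and 5.69. A gene whose group mean fell to this level was close to background. The number of arrays limits the precision of every value below.

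Some arrays stood apart in their controls. The separation of exon from intron control probe sets was 0.809 to 0.838 on day 1 replicate 2, day 3 replicate 1 and day 7 replicate 2, against 0.852 to 0.888 on the other 9 arrays. The labelling control dap was seen on day 3 replicate 1, day 7 replicate 2 and day 7 replicate 3, at 6.47 to 7.77, and lay at 2.13 to 2.89 on the others. The hybridisation control bioB was 7.53 to 7.72 on the intact arrays and 7.44 to 7.83 at day 3, but 8.62 to 10.29 at day 1 and 8.19 to 8.55 at day 7. The first principal component held 34.3% of the variance, and day 1 replicate 2 lay furthest out on it.

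**Figure D1:**
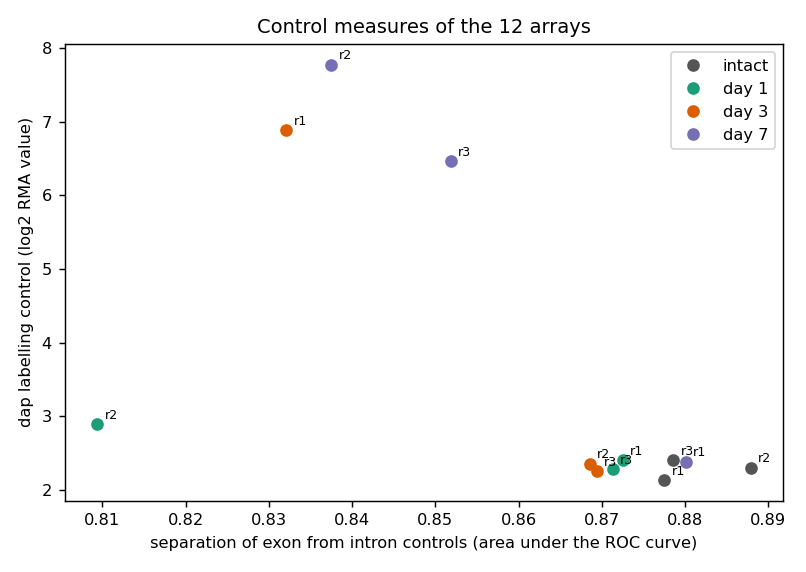
Control measures of the 12 arrays: the area under the curve that separates exon from intron control probe sets (x axis, no unit) against the dap labelling control (y axis, log2 RMA value), 1 point per array, coloured by group, r1 to r3 being the replicate. 3 arrays lie at 0.809 to 0.838 on the x axis, and 3 arrays lie at 6.47 to 7.77 on the y axis.

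The intact arrays carried the markers of alveolar macrophages. Siglecf averaged 8.79 ± 0.13 (log2, SD, n = 3), Pparg, a nuclear receptor that specifies these cells, 8.83 ± 0.11, the mannose receptor Mrc1 10.10 ± 0.05, and carbonic anhydrase Car4 10.09 ± 0.52. RNA of lung tissue cells was also present: Sftpc, the surfactant protein of type 2 cells, stood at 11.12 ± 0.27 and Scgb1a1, the secretoglobin of club cells, at 10.67 ± 0.66. The cytokine genes Tnf and Il1b were high in intact samples, at 10.88 ± 0.16 and 10.35 ± 0.43, as was Il6 at 9.65 ± 0.54.

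The first comparison asks how macrophages 1 day after resection differ from those of mice with an intact liver. Among the genes with the smallest unadjusted p on the lower side were some of connective tissue and lung epithelium: Adh1, an alcohol dehydrogenase, differed by -2.59 ± 0.35 (log2 difference ± SE, n = 3 per group), Col3a1, a chain of collagen III, by -1.77 ± 0.25, Sftpd, surfactant protein D, by -1.43 ± 0.21 and Mxra8, a membrane protein of matrix-rich tissue, by -1.67 ± 0.25. Scd1, the enzyme that desaturates stearoyl-CoA, differed by -2.29 ± 0.38 and Tppp3, a tubulin-binding protein, had a mean of 5.07 against 7.07 in intact samples. On the other side stood Saa3, an acute phase serum amyloid, at 2.98 ± 0.66, Mrgpra2b, a receptor of neutrophils, at 2.28 ± 0.42, Fkbp5, a co-chaperone induced by glucocorticoids, at 1.98 ± 0.34, and Slc40a1, the iron exporter ferroportin, at 1.53 ± 0.33. Fkbp5 stood apart from the glucocorticoid response list, which passed camera as lower at day 1, with a median of -0.32. That call was lost without intact replicate 3 (-0.29) and with an estimated correlation. G0s2, abundant in neutrophils, differed by 1.12 ± 0.23, and Gca, grancalcin, had a mean of 6.80 against 5.30. The other genes that the naming rule took were Scgn, Tmem144, Enho and Zfp786 on the higher side, between 0.69 and 0.89, and Rtl8b, Arrb1, Dpt and Ecscr on the lower side, between -1.66 and -1.12.

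None of these single genes passed the test at day 1. In limma, 0 of 22206 probe sets reached an adjusted p of 0.05, with a smallest adjusted p of 0.101, while 1985 had an unadjusted p under 0.05 (674 higher and 1311 lower) where 1110.3 are given by chance. The share of these that was higher was 34.0%, and 45.8% after quantile normalization or 47.6% after median centring. Without the 3 arrays of weakest control separation, an alternative chosen after the data were seen, 20 probe sets were higher and 51 lower at an adjusted p under 0.05. Leaving out single arrays gave 12 without day 3 replicate 1, 6 without day 1 replicate 3 and 1 without intact replicate 1.

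Markers of the tissue around the macrophages were lower as groups at day 1. Of the fibroblast and smooth muscle markers 16 of 17 were lower, with a median of -1.23 (camera adjusted p = 1.4e-09, adjusted p = 0.241 with an estimated correlation), among them Fbln1 at -1.28 ± 0.24 and Npnt at -2.39 ± 0.62. For the endothelium 15 of 16 markers were lower, with a median of -1.45 (adjusted p = 7.0e-08, adjusted p = 0.424 with an estimated correlation), as for Tie1 at -1.45 ± 0.27 and Kdr, a receptor of vascular endothelial growth factor, at -1.85 ± 0.52. All 13 markers of type 2 alveolar cells were lower (median -1.26, adjusted p = 1.0e-10, adjusted p = 0.248 with an estimated correlation), with Sftpc at -2.40 ± 0.75 and Muc1 at -1.09 ± 0.28. All 11 markers of type 1 alveolar cells were lower (median -1.40, adjusted p = 1.5e-07, adjusted p = 0.248 with an estimated correlation), with Cldn18 at -2.76 ± 0.68 and Ager at -1.70 ± 0.45. The airway epithelium was mixed: 10 of 14 markers were lower (median -0.61, adjusted p = 0.0246, adjusted p = 0.424 with an estimated correlation), with Krt8 at -0.89 ± 0.19, while the adhesion protein gene Epcam stood at 1.11 ± 0.39. Its call was lost without day 1 replicate 3 (-0.63) or without intact replicate 3 (-0.37). Day 1 replicate 2, the array with the weakest separation, enlarged these shifts. Without it the median was -0.77 for fibroblast, -0.80 for endothelial, -0.85 for type 1 and -0.36 for airway markers. Adjusted over the list alone, 8, 6, 9, 6 and 4 markers of these lists were lower, and 1 airway marker was higher, against 0 over all genes.

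Neutrophil markers moved the other way. At day 1, 15 of 19 were higher, with a median of 1.02 (adjusted p = 4.3e-08, adjusted p = 0.328 with an estimated correlation), and 10 passed when adjusted over the list alone, against 0 over all genes. Lcn2, an iron-binding lipocalin, differed by 1.41 ± 0.35 and Mmp9, a gelatinase, by 1.44 ± 0.34. Of the T and NK cell markers 12 of 19 were lower (median -0.23, adjusted p = 0.0184, adjusted p = 0.336 with an estimated correlation), with the granzyme genes Gzma at -2.39 ± 0.44 and Gzmb at -1.26 ± 0.29. This call was lost without day 1 replicate 3 (-0.16) or intact replicate 3 (-0.096). The median was -0.12 without intact replicate 1, and 3 members passed adjusted over the list alone. Dendritic cell markers were lower in 12 of 14 cases (median -0.58, adjusted p = 0.000373, adjusted p = 0.296 with an estimated correlation), as for Cd209a at -1.37 ± 0.36, and all 8 platelet markers were lower (median -0.66, adjusted p = 0.00021, adjusted p = 0.296 with an estimated correlation). Without day 1 replicate 2 these 2 medians were -0.34 and -0.34. Adjusted over the list alone, 4 dendritic cell and 1 platelet marker passed. Monocyte and interstitial macrophage markers were lower in 16 of 19 cases (median -0.44, adjusted p = 0.00221, adjusted p = 0.504 with an estimated correlation), among them Ly6c2, a surface protein of inflammatory monocytes, at -1.92 ± 0.44. This call was lost without day 1 replicate 2 (-0.17), and the median was -0.67 without day 1 replicate 3 and -0.26 without intact replicate 3.

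Groups of immune response, immediate early and growth factor genes were lower at day 1 too. The interferon response had 27 of 31 members lower, with a median of -0.57 (adjusted p = 3.4e-10, adjusted p = 0.249 with an estimated correlation), among them Ifit3 at -1.70 ± 0.33, Mx2 at -1.43 ± 0.34 and Igtp at -1.49 ± 0.36. All 14 genes of MHC class II presentation were lower (median -1.16, adjusted p = 8.0e-10, adjusted p = 0.234 with an estimated correlation), from Ciita, the master regulator of the class, at -1.05 ± 0.22 to H2-Ab1 at -2.34 ± 0.63. Of the immediate early genes 20 of 22 were lower (median -0.66, adjusted p = 1.8e-11, adjusted p = 0.219 with an estimated correlation), with the nuclear receptor genes Nr4a2 at -2.39 ± 0.44 and Nr4a3 at -0.93 ± 0.23 and with Ier3 at -1.45 ± 0.31. Growth and liver regeneration factors had 21 of 28 members lower (median -0.37, adjusted p = 0.000423, adjusted p = 0.219 with an estimated correlation), with hepatocyte growth factor Hgf at -1.43 ± 0.34, Tgfb2 at -0.65 ± 0.16 and Fgf1 at -1.32 ± 0.35. Adjusted over the list alone, 14, 11, 14 and 7 members of these 4 lists were lower and 1 immediate early gene was higher, against 0 over all genes. Without day 1 replicate 2, the array with the weakest separation, the median of MHC class II presentation was -0.69. That of the growth factors was -0.21 without intact replicate 1. RNA of lung tissue cells was on the arrays too, and its markers were lower. Whether the falls of these 4 lists come from the macrophages or from such cells was not tested. In all, 28 of 47 lists passed at day 1 (1 higher, 27 lower), and 0 passed with an estimated correlation or with fry. Without day 1 replicate 2, 61 of the 74 list calls of the 3 days stayed, 10 were lost and 3 turned sign. Those that turned, all at day 1, were NF-kB targets (0.11), heat shock (0.0065) and classical activation (0.013). The day 1 calls lost included inflammatory cytokines and chemokines (-0.055) and ribosomal proteins (-0.0073). Splits that mixed day 1 and intact arrays gave 18 to 25 lists.

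The second comparison asks the same of day 3. Col3a1 fell, from 4.92 ± 0.51 (SD, n = 3) in intact samples to 2.55 ± 0.25 at day 3 (probe set TC0100000343.mm.2, log2 difference -2.37 ± 0.25, adjusted p = 0.0135), to the level of background. The intact mean itself lay below the upper 95% limits of the intron controls. Dpt, the matrix protein dermatopontin, differed by -2.23 ± 0.29 with an adjusted p of 0.0545 and did not pass. Cd63, a tetraspanin of lysosomes and secretory granules, differed by 1.90 ± 0.26 (adjusted p = 0.0674), Saa3 by 3.04 ± 0.66, Slc40a1 by 1.83 ± 0.33 and Lcn2 by 1.59 ± 0.35. Ccr3, the eotaxin receptor, and Il5ra, the interleukin 5 receptor chain, both known from eosinophils, differed by 2.14 ± 0.48 and 1.57 ± 0.28. Histone genes were among those with the smallest unadjusted p on the lower side: H4c12 differed by -1.22 ± 0.21, H4c11 by -0.96 ± 0.15, and H3c14 and H3c15, whose values were identical on every array, by -1.04 ± 0.19. Of the other genes named by the rule, Tppp3, Mxra8, Ephb4 and Loxl1 lay between -2.18 and -1.21, and Myo5a, Mrgpra2b, Ptgr2 and Cxcr2 between 0.71 and 1.90.

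In limma 1 of 22206 probe sets passed at day 3, and 990 had an unadjusted p under 0.05 (435 higher, 555 lower), which is below the 1110.3 given by chance. Without the 3 weakly separating arrays 69 were higher and 183 lower. The count was 0 without intact replicate 2, intact replicate 3, day 3 replicate 2 or day 3 replicate 3, and it was 2 without intact replicate 1, 5 without day 3 replicate 1 and 7 without day 1 replicate 2.

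The same tissue markers were low at day 3. Of the fibroblast and smooth muscle markers 16 of 17 were lower (median -0.98, adjusted p = 9.6e-13, adjusted p = 0.219 with an estimated correlation), of which Col3a1 passed over all genes and 5 passed adjusted over the list alone, as did Fbln1 at -1.20 ± 0.24 and Col1a2 at -1.21 ± 0.38. All 16 endothelial markers were lower (median -1.10, adjusted p = 9.2e-10, adjusted p = 0.344 with an estimated correlation), with Tie1 at -1.32 ± 0.27 and Ramp2 at -2.05 ± 0.83. Type 2 cell markers were lower in 12 of 13 cases (median -0.80, adjusted p = 2.8e-07, adjusted p = 0.302 with an estimated correlation), with Sftpd at -1.09 ± 0.21 and Sftpa1 at -1.51 ± 0.69, and airway markers in 13 of 14 (median -0.51, adjusted p = 1.8e-05, adjusted p = 0.219 with an estimated correlation), with Scgb1a1 at -1.48 ± 0.36. The endothelial median was -0.61 without day 3 replicate 2, that of type 2 cells -1.21 without day 3 replicate 1 and that of the airway -0.33 without intact replicate 3. Type 1 cell markers did not pass (median -0.38, adjusted p = 0.0598). Adjusted over the list alone, 1 endothelial, 1 type 2 and 3 airway markers were lower.

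Neutrophil markers had a median of 0.92 at day 3 (15 of 19 higher, adjusted p = 2.7e-09, adjusted p = 0.296 with an estimated correlation), and 5 passed adjusted over the list alone, against 0 over all genes. Mmp9 stood at 1.46 ± 0.34 and the chemokine receptor gene Cxcr2 at 1.35 ± 0.31. The eosinophil list did not pass (median 0.16, adjusted p = 0.637): beside Ccr3 and Il5ra, which passed adjusted over the list alone, the granule protein genes Prg2 and Epx differed by -1.55 and -1.53, Epx being picked out after its values were seen. Complement genes were higher in 9 of 14 cases (median 0.32, adjusted p = 0.0301, adjusted p = 0.549 with an estimated correlation), led by the C3a receptor gene C3ar1 at 1.71 ± 0.48 and Cd55 at 1.05 ± 0.42. This call was lost without day 3 replicate 2 (0.039), day 3 replicate 3 (0.21), day 1 replicate 2 (0.32), intact replicate 1 (0.36) or intact replicate 2 (0.28). Cxcl13, a chemokine that attracts B cells, differed by 2.56 ± 0.64 and Ccl5, which attracts T cells, by -1.38 ± 0.28.

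Cell cycle genes were lower in 34 of 37 cases at day 3 (median -0.33, adjusted p = 1.5e-08, adjusted p = 0.388 with an estimated correlation), as for Ube2c at -1.38 ± 0.51 and Aurkb at -0.57 ± 0.24, with 0 passing adjusted over the list alone. The interferon response had 27 of 31 members lower (median -0.39, adjusted p = 1.0e-06, adjusted p = 0.344 with an estimated correlation), with Cxcl10 at -1.44 ± 0.46 and Igtp at -1.25 ± 0.36. For the immediate early genes the number was 19 of 22 (median -0.32, adjusted p = 7.4e-07, adjusted p = 0.248 with an estimated correlation), with Nr4a1 at -0.72 ± 0.17 and Myc at -0.92 ± 0.29. MHC class II presentation had 12 of 14 members lower (median -0.55, adjusted p = 2.4e-05, adjusted p = 0.315 with an estimated correlation), with H2-Ab1 at -1.62 ± 0.63. Adjusted over the list alone, 0 interferon genes, 1 immediate early gene and 0 class II genes passed. Dendritic cells and monocytes, which also carry class II, moved with it. Dendritic cell markers were lower in 13 of 14 cases (median -0.26, adjusted p = 5.6e-05, adjusted p = 0.247 with an estimated correlation), with a median of -0.16 without intact replicate 1 and -0.48 without intact replicate 2. Monocyte and interstitial macrophage markers were lower in 13 of 19 (median -0.35, adjusted p = 0.00852, adjusted p = 0.549 with an estimated correlation), a call lost without intact replicate 3 (-0.43). Without intact replicate 3 the cell cycle median was -0.53, and without day 3 replicate 2 that of the interferon response was -0.25. Mcpt8, a protease of basophils, differed by -2.63 ± 0.68 within a mast cell and basophil list of which 9 of 11 were lower (median -0.51, adjusted p = 0.00017, adjusted p = 0.252 with an estimated correlation). In all, 23 of 47 lists passed at day 3 (2 higher, 21 lower), and 0 with an estimated correlation or with fry.

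The final comparison with intact samples was day 7, where 4 genes fell. Sftpd fell from 4.52 ± 0.37 (SD, n = 3) to 2.54 ± 0.05 (TC1400001790.mm.2, log2 difference -1.98 ± 0.21, adjusted p = 0.00965), and Col3a1 from 4.92 ± 0.51 to 2.82 ± 0.25 (-2.10 ± 0.25, adjusted p = 0.0249). Mxra8 fell from 4.28 ± 0.14 to 2.32 ± 0.28 (TC0400002095.mm.2, -1.97 ± 0.25, adjusted p = 0.0271) and Dpt from 5.67 ± 0.48 to 3.44 ± 0.16 (TC0100001510.mm.2, -2.23 ± 0.29, adjusted p = 0.0271). The day 7 means of Sftpd, Col3a1 and Mxra8 lay at about the intron control median, and their intact means lay below the upper 95% limits of these controls, from 5.01 to 5.69. Background therefore limits the size of these falls. Among genes that did not pass, Gzma differed by -2.60 ± 0.44, Icos, a co-stimulatory receptor of T cells, by -1.77 ± 0.27, Ccl5 by -1.64 ± 0.28, Adh1 by -2.25 ± 0.35, and the interferon-induced genes Ifit3 and Ifit3b by -1.89 ± 0.33 and -1.91 ± 0.29. On the higher side Ccr3 differed by 2.71 ± 0.48, Mrgpra2b by 2.63 ± 0.42, the stefin gene Stfa2 by 2.53 ± 0.45, Mmp9 by 1.95 ± 0.34 and Cxcr2 by 1.71 ± 0.31. The other genes on that side were Cstdc6, Stfa2l1, Cstdc5, Slc40a1 and Padi4, between 1.04 and 2.31.

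In limma 0 probe sets were higher and 4 lower of 22206 at day 7, and 1265 had an unadjusted p under 0.05 (434 higher, 831 lower). The higher share of these was 34.3%, and 47.5% after quantile normalization or 53.1% after median centring. Without the 3 weakly separating arrays 47 were higher and 233 lower, and among the 9 arrays without the dap control, which hold 1 day 7 array, the count was 0. It was 0 without day 7 replicate 2, day 7 replicate 3 or intact replicate 2, 1 without intact replicate 3 or day 1 replicate 3, and 2 without day 1 replicate 1, day 7 replicate 1 or day 3 replicate 2. It was 8 without day 3 replicate 1 and 18 without day 1 replicate 2.

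**Figure D2:**
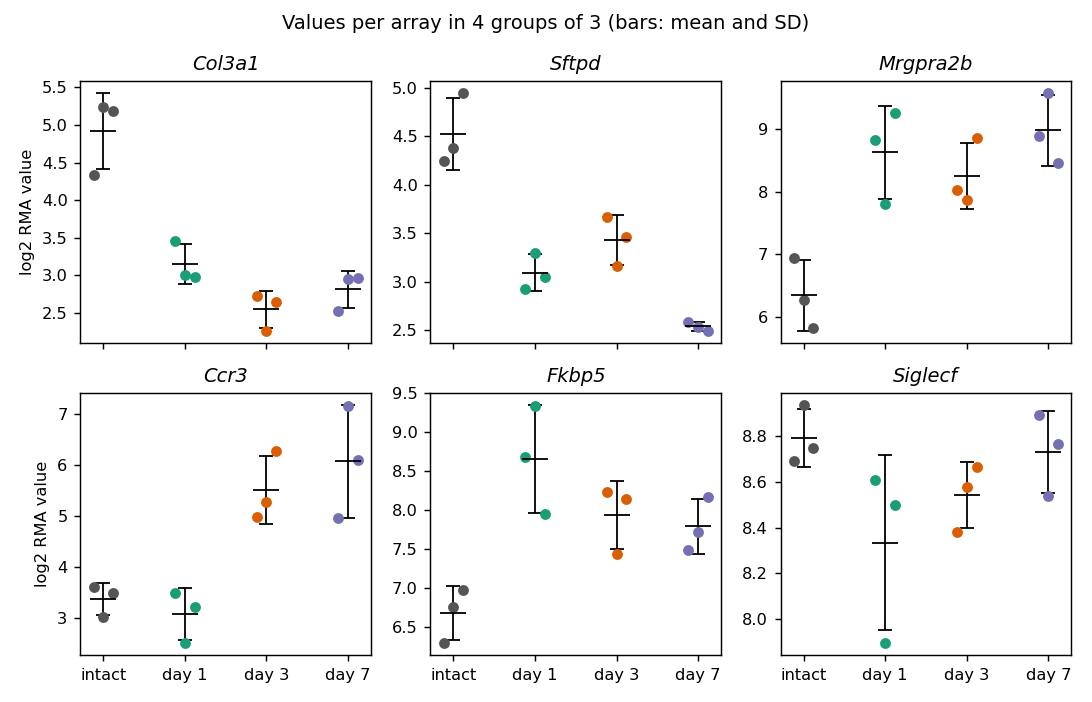
Values of 6 genes on each array (points, log2 RMA value on the y axis) in the 4 groups of 3 arrays (x axis), with the group mean and SD as bars. Col3a1 lies at a mean of 4.92 in intact samples and 2.55 at day 3, Sftpd at 4.52 and 2.54 in intact and day 7 samples, and Siglecf stays within 8.33 and 8.79 in its 4 group means.

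At day 7 all 17 fibroblast and smooth muscle markers were lower (median -0.89, adjusted p = 1.9e-11, adjusted p = 0.219 with an estimated correlation), with Tcf21, a regulator of lung fibroblasts, at -1.33 ± 0.32 and Gsn at -1.36 ± 0.38. All 16 endothelial markers were lower (median -1.19, adjusted p = 8.8e-11, adjusted p = 0.315 with an estimated correlation), with Emcn at -1.63 ± 0.47. All 13 type 2 cell markers were lower (median -1.28, adjusted p = 8.8e-11, adjusted p = 0.248 with an estimated correlation), with Muc1 at -1.59 ± 0.28 and Sftpa1 at -2.11 ± 0.69. All 11 type 1 cell markers were lower (median -0.76, adjusted p = 4.9e-07, adjusted p = 0.248 with an estimated correlation), with Emp2 at -1.73 ± 0.45. Of the airway markers 13 of 14 were lower (median -0.91, adjusted p = 1.3e-08, adjusted p = 0.219 with an estimated correlation), with Scgb1a1 at -2.03 ± 0.36 and Bpifa1 at -1.75 ± 0.35, and Epcam again stood apart at 1.70 ± 0.39. Adjusted over the list alone, 8, 3, 3, 5 and 8 markers of these lists were lower, against Col3a1 and Sftpd over all genes, and Epcam was higher.

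Neutrophil markers were higher in 17 of 19 cases at day 7, with a median of 1.21 (adjusted p = 4.0e-17, adjusted p = 0.219 with an estimated correlation), and 12 passed adjusted over the list alone, against 0 over all genes. The eosinophil list passed at this day (7 of 12 higher, median 0.16, adjusted p = 0.00393, adjusted p = 0.442 with an estimated correlation), through Ccr3, Il5ra at 1.24 ± 0.28, Siglece at 1.13 ± 0.39 and Ear6 at 0.77 ± 0.31, and 2 passed adjusted over the list alone. The call was lost without day 7 replicate 2 (0.069), and without intact replicate 1 the median turned to -0.06. It was 0.39 without day 7 replicate 1, 0.045 without day 7 replicate 3, 0.30 without intact replicate 2 and 0.50 without intact replicate 3. T and NK cell markers were lower in 14 of 19 cases (median -0.27, adjusted p = 9.6e-05, adjusted p = 0.219 with an estimated correlation), of which 2, Gzma and Gzmb, passed adjusted over the list alone. Cxcl13 differed by 2.44 ± 0.64, Ly6c2 by -1.98 ± 0.44 and Mcpt8 by -2.57 ± 0.68.

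The interferon response had 25 of 31 members lower at day 7 (median -0.50, adjusted p = 9.2e-10, adjusted p = 0.253 with an estimated correlation), with Mx2 at -1.48 ± 0.34 and Gbp3 at -1.10 ± 0.27, and 5 passed adjusted over the list alone. MHC class II presentation had 13 of 14 members lower (median -0.62, adjusted p = 0.00053, adjusted p = 0.424 with an estimated correlation), while its co-stimulatory member Cd80 stood at 0.88 ± 0.28. Dendritic cell markers were again lower in 12 of 14 cases (median -0.16, adjusted p = 0.00456, adjusted p = 0.392 with an estimated correlation). Their call was lost without day 7 replicate 3 (-0.14) or intact replicate 1 (-0.17), and the median was -0.30 without intact replicate 2. Monocyte and interstitial macrophage markers were lower in 12 of 19 (median -0.22, adjusted p = 0.0262, adjusted p = 0.641 with an estimated correlation). This call was lost without day 7 replicate 3 (-0.0088) or intact replicate 3 (-0.26), and the median was -0.42 without day 7 replicate 1. Immediate early genes had a median of -0.22 (18 of 22 lower, adjusted p = 0.00515, adjusted p = 0.463 with an estimated correlation), with Ier3 at -1.19 ± 0.31. Neither the class II nor the immediate early list had a member past the threshold adjusted over the list alone. Cell cycle genes were higher in 26 of 37 cases (median 0.14, adjusted p = 0.0219, adjusted p = 0.747 with an estimated correlation), with Kif11 at 0.94 ± 0.33 and Prc1 at 0.79 ± 0.24. Their median turned to -0.07 without day 7 replicate 1 and to -0.01 without intact replicate 3, and was 0.31 without day 7 replicate 2 and 0.24 without intact replicate 1. The interferon median was -0.33 without day 7 replicate 2 and that of the immediate early genes -0.14 without day 7 replicate 3. In all, 23 of 47 lists passed at day 7 (4 higher, 19 lower), and 0 with an estimated correlation or with fry.

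**Figure D3:**
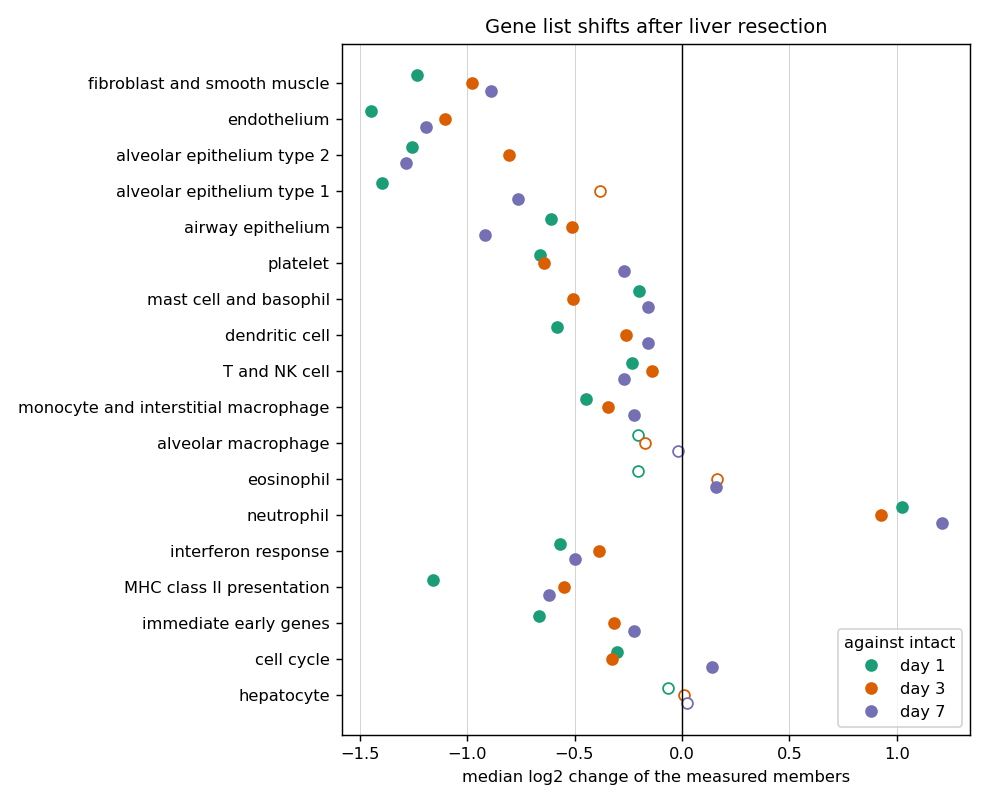
Median log2 change of the measured members (x axis) of 18 gene lists (y axis) at each day against intact samples, with filled points where the list passed camera with a preset correlation and open points where it did not. Fibroblast and smooth muscle markers lie at -1.23, -0.98 and -0.89 at days 1, 3 and 7, and neutrophil markers at 1.02, 0.92 and 1.21.

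Of the 47 lists, 15 were lower and 1, the neutrophil list, was higher at all 3 days with the preset correlation, and 15 passed at no day. With an estimated correlation 0 passed at any day (smallest adjusted p = 0.219). The alveolar macrophage list was among the lists that passed at no day, with medians of -0.20, -0.17 and -0.02 at days 1, 3 and 7 (adjusted p = 0.158, 0.0655 and 0.625). Siglecf itself differed by -0.46 ± 0.20, -0.25 ± 0.20 and -0.06 ± 0.20, the last turning to 0.04 without day 7 replicate 2 and 0.01 without intact replicate 2. Marker lists of hepatocytes (medians -0.07, 0.01 and 0.02), erythroid cells (-0.09, 0.08 and 0.05) and B cells (-0.17, -0.11 and -0.13) did not pass either. The mean of the list had the other sign than its median for alveolar macrophages at day 7 (0.01), hepatocytes at day 3 (-0.01) and erythroid cells at day 7 (-0.07). None of the 17 genes fixed for every day passed; they ranged from -2.41 to 1.98 at day 1, from -1.40 to 1.26 at day 3 and from -1.63 to 1.12 at day 7. The lowest was Il6 at each day, at -2.41 ± 0.79, -1.40 ± 0.79 and -1.63 ± 0.79, and the highest was Fkbp5, at 1.98 ± 0.34, 1.26 ± 0.34 and 1.12 ± 0.34. Hgf, below intact at day 1, stood at 0.06 ± 0.34 at day 3, or -0.17 without day 3 replicate 2, and at -0.60 ± 0.34 at day 7.

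The days were also compared with each other. Between day 3 and day 1, Apobec1, an RNA-editing deaminase, differed by 1.38 ± 0.21, Fgl2, a fibrinogen-like protein, by 1.70 ± 0.27, Cd63 by 1.62 ± 0.26, the proton-sensing receptor gene Gpr65 by 1.85 ± 0.31 and Il5ra by 1.68 ± 0.28, while Ear6, Selenov, Mdk, Tpbgl and Rims2 lay between -1.41 and -0.84. Between day 7 and day 3, Cdo1, which oxidises cysteine, differed by -2.39 ± 0.35, Cd63 by -1.27 ± 0.26, and Igf2r, Cpq and Zfp354c by -1.28 to -0.79, against the histone genes H2ac10 at 1.34 ± 0.19, H1f3 at 1.24 ± 0.19, H3c14 and H3c15 at 1.18 ± 0.19 and H4c11 at 1.02 ± 0.15. Between day 7 and day 1, Ccr3 differed by 3.00 ± 0.48, Cd80 by 1.56 ± 0.28, Bank1 by 1.73 ± 0.31, Nuf2 by 1.04 ± 0.20 and the cholesterol transporter gene Abca1 by 0.99 ± 0.19, against Reg3g, an antimicrobial lectin, at -2.01 ± 0.44 and Enho, Pcp2, Safb and Il27 between -0.94 and -0.75.

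No probe set passed limma's test in any of these 3 comparisons: the smallest adjusted p were 0.242, 0.114 and 0.573, and 2132 (1403 higher), 1138 (450 higher) and 1497 (846 higher) had an unadjusted p under 0.05. After quantile normalization the share that was higher moved from 65.8% to 53.4% between day 3 and day 1, and from 39.5% to 50.8% between day 7 and day 3, where median centring gave 56.4%. Without day 3 replicate 1 the counts were 3, 3 and 0, and without day 1 replicate 3 the first was 1. Over all 4 groups the moderated F test passed Col3a1 and Sftpd, 2 probe sets with an adjusted p of 0.0409, while 1629 had an unadjusted p under 0.05. This number was 8 without day 3 replicate 1, 6 without day 1 replicate 2, 4 without day 7 replicate 1, 1 without day 1 replicate 3 or intact replicate 1, and 0 without any other single array.

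All 3 days were set against the same 3 intact arrays, which alone makes their changes resemble each other. Across genes, which are not independent replicates, the changes of days 1 and 3 correlated at 0.458, those of days 1 and 7 at 0.598 and those of days 3 and 7 at 0.583. Unchanged groups simulated against the shared arrays gave 0.480, 0.445 and 0.466. The covariances were 0.0494, 0.0706 and 0.0535, against 0.0422, 0.0398 and 0.0435 in the simulation, and all 3 lay below the upper limits of the simulated range, at 0.0968, 0.0943 and 0.110. The 3 intact arrays are too few to be split between the comparisons, so part of any excess may come from the shared arrays.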

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

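Apart from the regroupings of arrays, the tests of explanations below were chosen after the results were seen.

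Between days, 22 of the 141 list differences passed camera with the preset correlation, and none did with an estimated correlation (lowest adjusted p = 0.997). From day 1 to day 3 the median difference was 0.36 for the interferon response, 0.31 for glucocorticoid response, 0.34 for immediate early genes (0.335), 0.42 for complement, 0.54 for MHC class II presentation, 0.57 for type 2 and 0.75 for type 1 alveolar cells. From day 3 to day 7 it was 0.50 for cell cycle genes (adjusted p = 1.4e-13), 0.17 for alveolar macrophage, 0.41 for eosinophil and 0.36 for neutrophil markers, and -0.36 and -0.62 for type 2 and type 1 alveolar cells. From day 1 to day 7 it was 0.30 for NF-kB feedback and targets, 0.39 for immediate early genes, 0.44 for cell cycle genes, 0.59 for MHC class II presentation, 0.20 for pattern recognition receptors, 0.23 for chemokine and growth factor receptors, 0.37 for eosinophil and 0.32 for neutrophil markers, and -0.47 for the airway epithelium. These values rest on few arrays: 4 of the 22 passed without each single array in turn. They were type 1 markers from day 1 to day 3, cell cycle genes from days 1 and 3 to day 7 and immediate early genes from day 1 to day 7. The values that follow ended a call or moved by more than 1.5 times. Without day 1 replicate 2, which separates weakly, 11 of 22 passed. From day 1 to day 3 the median was then 0.10 for the interferon response, 0.16 for glucocorticoid response, 0.19 for immediate early genes, 0.15 for complement, 0.13 for MHC class II presentation and -0.16 for type 2 cells, none of which passed. From day 1 to day 7 it was -0.16 for NF-kB targets, 0.077 for MHC class II, 0.076 for pattern recognition, 0.044 for chemokine receptors and 0.053 for neutrophil markers, none past the threshold. It was 0.21 for immediate early genes and 0.22 for eosinophil markers, which passed. Without day 3 replicate 1, also weak, the values from day 1 to day 3 were 0.18 for interferon, 0.27 for glucocorticoid response and 0.20 for type 2 cells, not passing, and 0.22 for type 1 cells. Those from day 3 to day 7 were -0.20 for type 1, -0.074 for type 2, 0.080 for alveolar macrophage and 0.23 for eosinophil markers, not passing. Of the other arrays, leaving out day 7 replicate 2 ended the calls of NF-kB targets (0.20), eosinophil (0.31) and neutrophil markers (0.14) from day 1, of eosinophil (0.20) and neutrophil markers (0.27) from day 3 and of complement (0.42). It gave 0.29 for alveolar macrophage markers. Without day 7 replicate 1 the calls from day 1 of MHC class II (0.39), NF-kB targets (0.33), chemokine receptors (0.18), neutrophil (0.22) and pattern recognition (0.048) and from day 3 of type 1 (-0.34), type 2 (-0.36) and alveolar macrophage (0.058) ended. Cell cycle genes stood at 0.19 from day 1 and 0.30 from day 3 and eosinophil markers at 0.58 from day 1. Without day 7 replicate 3 those of airway (-0.46), type 2 (-0.12), alveolar macrophage (0.14), eosinophil from day 3 (0.34) and complement (0.42) ended. Neutrophil markers stood then at 0.52 from day 1 and 0.60 from day 3. Without day 3 replicate 2 those of complement (0.31), pattern recognition (0.20), alveolar macrophage (0.21), eosinophil (0.34) and neutrophil markers (0.21) from day 3 ended. Type 2 cells stood at -0.63. Without day 3 replicate 3 those of complement (0.53), immediate early genes (0.24) and interferon (0.27) ended. Eosinophil markers stood at 0.68 and neutrophil markers at 0.62 from day 3. Without day 1 replicate 1 those of complement (0.64), glucocorticoid response (0.31), airway (-0.49), chemokine receptors (0.33), eosinophil (0.53), pattern recognition (0.20) and, from day 3, type 2 (-0.36), alveolar macrophage (0.17) and eosinophil (0.41) ended. Without day 1 replicate 3 the values were 1.38 for type 1, 1.17 for type 2 and 0.86 for complement at day 3. They were 0.41 for chemokine receptors, 0.78 for eosinophil and 0.49 for neutrophil markers at day 7.

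Control probe sets outside the comparisons stood more than 1 log2 unit above the highest intact array. The labelling controls dap, phe and thr were at 7.77, 5.47 and 5.73 on day 7 replicate 2, at 6.47, 3.80 and 4.22 on day 7 replicate 3, and at 6.88, 4.22 and 3.64 on day 3 replicate 1, against at most 2.40, 2.42 and 2.41 in intact arrays. The hybridisation control bioB was 10.29 on day 1 replicate 2, against at most 7.72.

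Regrouping 6 arrays makes 10 splits, too few for a share under 0.05. The number of probe sets was 0 at day 1 (highest other split 0), 1 at day 3 (0) and 4 at day 7 (0), so that 10, 1 and 1 of the 10 splits gave as many. It was 0 for days 3 and 1 (highest other 1), days 7 and 3 (0) and days 7 and 1 (1), where 10 of 10 gave as many. The number of lists was 28 at day 1, 23 at day 3 and 23 at day 7, reached by 1, 2 and 1 splits. The other splits gave 18 to 25, 7 to 24 and 5 to 21 lists. They mix intact and resected arrays in each group. A list that passes camera with the preset correlation therefore does not by itself show a difference between groups of mice. Of 100 groupings of the 12 arrays, the real one included, 3 gave as many probe sets in the F test as the real one. The count was 2 in the real grouping and 112 in the highest other. This share does not exclude chance, since the arrays differ in spread, with array weights from 0.19 to 2.32, and are not interchangeable. The count of 2 also fell to 0 without some single arrays. A grouping with 112 points to a structure of the arrays besides their groups. The grouping with 18 put day 1 replicate 2, day 7 replicate 2 and day 3 replicate 1 together, the weakly separating arrays, and without these the real grouping gave 281, or 3 with the labelling control as a block.

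Markers of structural lung cells (5 lists: fibroblast and smooth muscle, endothelium, both alveolar epithelia and airway) were lower after resection. None of these lists passed camera with an estimated correlation, and type 1 markers did not pass at day 3 with the preset correlation either. The tables argue against a product of the weakly separating arrays, without which the mean score of resected arrays minus intact was -0.97 ± 0.21 (SE). They also argue against a product of the arrays with dap, since the score differed by -1.05 ± 0.25 among arrays without dap. A labelling batch that dap does not mark, such as one of the 3 intact arrays, was not tested. A hybridisation level set apart at days 1 and 7 is argued against less firmly by day 3, whose bioB overlapped intact: it differed by -0.76 ± 0.34, but by -0.57 ± 0.40 without day 3 replicate 2, -0.67 ± 0.49 without day 3 replicate 3, -0.72 ± 0.42 without intact replicate 2 and -0.62 ± 0.35 without intact replicate 3, each within 2 SE of 0, and by -1.03 ± 0.21 without day 3 replicate 1, the array of weak separation with dap, and -0.94 ± 0.30 without intact replicate 1, both beyond 2 SE. Less RNA of structural cells beside the sorted macrophages is a candidate source, as a hypothesis that stays open. In the mean of the 3 days 69 of 71 markers (97.2%) were lower, among them ones of high signal such as Sftpc, at 11.12 in intact arrays. This share restates the pattern and cannot separate fewer such cells from a change of expression in them. The Siglec-F bead sort is meant to remove these cells, but the Sftpc signal shows that some of their RNA stayed in the intact samples. The purity of the sort is not given, and a difference in its yield was not tested.

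Neutrophil markers were higher after resection, though their list passed at no day with an estimated correlation. Their score differed by 0.94 ± 0.17 without the weakly separating arrays, 0.85 ± 0.22 among arrays without dap and 0.71 ± 0.27 at day 3. This argues against the weakly separating arrays, the arrays with dap and, less firmly, the hybridisation level as sources. Day 3 stood at 0.47 ± 0.17 without day 3 replicate 3 and at 0.76 ± 0.45, within 2 SE of 0, without day 3 replicate 1. It lay between 0.64 and 0.91, beyond 2 SE, without any other of the 6 arrays. A lower share of macrophages alone is also argued against, since the structural markers moved the other way, by -0.96 ± 0.24. More RNA of neutrophils may be a source, but this stays open: 15 of 19 markers (78.9%, binomial SE 9.35) were higher, just under the bound of 80%, and the margin that leaves it undecided was added after that share was seen. Markers of high signal did not move alike, though signals of different probe sets do not rank the abundance of their transcripts. Retnlg, Lcn2, S100a8 and S100a9, with means of 11.44, 10.76, 9.38 and 9.25, differed by 1.08, 1.45, 1.12 and 1.07. Trem1, also at 9.25, differed by 0.06, Csf3r and Ngp, both at 8.69, by 0.72 and -0.09, and the dimmer Camp, Ltf and Elane by -0.67 to -0.14. The bead sort for Siglec-F is meant to remove neutrophils, but its purity is not given, and the neutrophil score was 6.69 on the intact arrays too.

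Ccr3 and Il5ra had higher values at days 3 and 7. Their mean differed by 1.72 ± 0.39 among arrays without dap and by 1.79 ± 0.30 without the weakly separating arrays, which argues against both sources. For day 7 the point about dap rests on replicate 1 alone, at 4.04, against 4.95 and 5.78 on the arrays with dap and 2.95 in intact samples. Il5ra lay at 2.53, 4.10 and 3.77 in intact, day 3 and day 7 samples, and Ccr3 at 3.37 in intact ones. These means lie below the upper 95% limits of the intron controls, from 5.01 to 5.69. Eosinophils carry Siglec-F, so the sort would keep them, and more RNA of these cells may be a source. The other 10 eosinophil markers differed by -0.086 ± 0.29 in their mean, which decides neither way. Those of highest signal in intact arrays, Slc6a4 at 7.99, Prg2 at 7.52 and Ear6 at 7.29, differed by -0.86, -1.55 and -0.38 at day 3 and by -0.20, -0.27 and 0.77 at day 7. Signals of different probe sets do not rank the abundance of their transcripts, so these values do not decide it either.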

How the results depend on the processing

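Genes past the threshold in the 6 comparisons and the F test, and lists past it, depended on the settings as follows; the cause was not tested unless stated. With trend and robust moderation the count was 4 at day 3 and 6 in F, and with no moderation 0 at day 3, day 7 and in F. Without probe sets below the median level the count was 3 at day 3 and 7 at day 7, with 12 lists at day 1 and 15 at day 7. Lists lose members under this filter, and whether that ended the calls was not tested. Without probe sets below the lower quartile the count was 3 at day 3. Quantile normalization gave 4 at day 3. With only the compared groups it was 0 at day 3 and 48 at day 7. Array weights gave 43, 298 and 402 at days 1, 3 and 7, 7 for days 7 and 3, and 360 in F. An unadjusted p under 0.05 with a fold of at least 2 gave 412, 193 and 320 against intact, 268, 117 and 122 for days 3 and 1, 7 and 3, and 7 and 1, and 541 in F. An adjusted p under 0.1 gave 5 at day 3, 8 at day 7 and 4 in F, and 1 probe set per gene gave 2 at day 3. With an estimated correlation or with fry 0 lists passed at each day (8, 7 and 8 had an unadjusted p under 0.05 with the former).

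Of the settings chosen after seeing the data, leaving out the 3 weakly separating arrays gave 71, 252 and 280, 6 for days 3 and 1, 4 for days 7 and 3, and 281 in F. The labelling control as a block gave 1 at day 1. The 9 arrays without it gave 0 at day 7 and in F, with 1 array at day 7 that is assumed to vary like the other groups. Leaving out the 4 arrays of either kind gave 129, 329 and 96, 31, 13 and 2 between days and 360 in F, again with 1 array at day 7, so the 96, 13 and 2 rest on that array.

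Without single arrays the counts ran from 0 to 12 at day 1, 0 to 7 at day 3, 0 to 18 at day 7, 0 to 3 for days 3 and 1, 0 to 3 for days 7 and 3, 0 to 0 for days 7 and 1 and 0 to 8 in F, and lists from 19 to 31, 19 to 24 and 19 to 25. The adjusted p of the called genes ran over all settings from 0.000208 to 0.269 for Col3a1 at day 3 and from 0.00156 to 0.430 at day 7, from 0.000415 to 0.406 for Sftpd, from 0.000415 to 0.496 for Mxra8 and from 0.000778 to 0.572 for Dpt.

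The replicate numbers did not pair the arrays: 3 of 18 pairs of the same number had residual correlations over 0.1 (range -0.241 to 0.258), and 3 of 12 arrays lay closest to their own number. With the replicate block the count was 0 at day 3, 8 at day 7 and 0 in F, and 74 of 74 list calls kept their direction.

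Over the settings, named genes gave 5520 values on the same side as before and 63 of other sign. A further 44 were no longer past the threshold and 341 were newly past it. Lists gave 1359, 32, 311 and 0 in that order. Only lists that had passed were followed, so the 0 newly past was fixed beforehand and does not show that no list was added. Without probe sets below the median level the sign turned for T and NK cells at day 3 (0.071). Quantile normalization turned Fabp4 (0.18) and Il1b (0.041) at day 1 and Pparg (0.019) at day 7, and median centring Fabp4 at day 1 (0.0089), Pparg (0.0295) and Tnf (0.013) at day 7. Array weights turned Fabp4 (0.52), Il1b (0.077), Tnf (0.0465), Il10 (0.45), NF-kB targets (0.047) and classical activation (0.032) at day 1, and Pparg (0.060) and pattern recognition (-0.0088) at day 7. Without single arrays these values changed sign, running at day 1 from -0.15 to 0.41 for Marco, -0.40 to 0.59 for Fabp4, -0.33 to 0.097 for Il1b, -0.31 to 0.0755 for Tnf, -0.55 to 0.63 for Il10, -0.41 to 0.11 for NF-kB targets, -0.44 to 0.0065 for heat shock and -0.82 to 0.013 for classical activation. At day 3 they ran from -0.48 to 0.0080 for Fabp4, -0.48 to 0.025 for ribosomal proteins and -0.17 to 0.21 for Hgf. At day 7 they ran from -0.21 to 0.22 for Itgax, -0.066 to 0.31 for cell cycle, -0.14 to 0.037 for Siglecf, -0.0887 to 0.11 for Pparg, -0.40 to 0.15 for Car4, -0.13 to 0.046 for Tnf, -0.0585 to 0.50 for eosinophil markers and -0.0515 to 0.37 for Il1b.

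Among the added settings, leaving out the 3 arrays turned Fabp4 (0.59), Il1b (0.072), Tnf (0.0755), Il10 (0.63), NF-kB targets (0.11), heat shock (0.0065) and classical activation (0.013) at day 1, ribosomal proteins (0.025) at day 3, and Siglecf (0.037), Pparg (0.11) and Car4 (0.15) at day 7. The block turned Siglecf (0.10), Pparg (0.099), Mrc1 (-0.20), oxidative phosphorylation (0.12) and monocytes (0.0090) at day 7. The 9 arrays turned ribosomal proteins (0.025) at day 3, and at day 7 Siglecf (0.10), Pparg (0.10), Car4 (0.29), Mrc1 (-0.040), Il1b (-0.017), Tnf (0.067), Il10 (0.31), Arg1 (-0.16), heat shock (0.027), oxidative phosphorylation (0.12), MHC class I (0.0019), circadian clock (0.029) and monocytes (0.16). Leaving out 4 arrays gave the first set of values at days 1 and 3 and the last at day 7. Genes near the intron control median, between 2.39 and 2.76, lie close to background, so the size of a fall to that level is limited by it.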

Other observations

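The tests in this part were chosen after the results were seen, and the regrouping of arrays was applied to a pooling added after the data were seen. When all 9 arrays after resection were set against the 3 intact arrays in limma, 27 of 22206 probe sets passed (4 higher, 23 lower). An unadjusted p under 0.05 was found for 1120, close to the 1110.3 given by chance. The 4 higher genes were Mrgpra2b (2.27 ± 0.35, adjusted p = 0.0349), the iron exporter gene Slc40a1 (1.64 ± 0.26), Mmp9 (1.62 ± 0.29) and Gca (1.37 ± 0.24). Among the lower were the matrix genes Col3a1 (-2.08 ± 0.23, adjusted p = 0.00562), Mxra8 (-1.77 ± 0.21), Dpt (-2.04 ± 0.26), Fbln1 (-1.18 ± 0.19) and Loxl1 (-1.04 ± 0.18), the collagen chaperone gene Serpinh1 (-1.45 ± 0.24) and the vascular genes Tie1 (-1.30 ± 0.22), Ephb4 (-1.38 ± 0.19) and Ecscr (-1.55 ± 0.23). Genes of lymphocytes and monocytes were lower too: Gzma (-2.30 ± 0.37), Gzmb (-1.35 ± 0.23), Icos (-1.47 ± 0.23), Ccl5 (-1.39 ± 0.24) and Ly6c2 (-1.93 ± 0.34). The intact means of Col3a1, Mxra8, Fbln1, Loxl1, Serpinh1, Ephb4, Ecscr and Gzmb lay between 3.57 and 4.93. That is below the upper 95% limits of the intron controls, from 5.01 to 5.69, so background limits these falls. Tie1, Dpt, Icos and Ccl5 lay within these limits, and Gzma (5.81) and Ly6c2 (9.19) above them. For each of the 27 all 9 resected arrays lay on one side of the 3 intact arrays. Of 100 of the 220 splits of 9 against 3 arrays, 1, the real one, gave as many, and the highest other gave 3. The pooling was chosen after the data were seen, so this share does not exclude chance. It also cannot tell resection from any other feature that the 3 intact arrays share. By exact permutation of list scores over the 220 splits, 0 of 47 lists passed (lowest adjusted p = 0.0610, smallest possible p = 0.00455).

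Without the 3 weakly separating arrays, which leaves 2 arrays in each resected group, single genes that rose at day 3 included Apoe by 3.11 ± 0.22, Mmp12, a macrophage elastase, by 2.67, Mfge8, which bridges dying cells to phagocytes, by 2.38, Apoc1 by 2.19 and C3ar1 by 2.13. With all arrays these genes differed by 2.01, 2.27, 1.44, 1.42 and 1.71, and none passed. They are no tested group: with all arrays the lipid efflux and storage list did not pass at day 3 (median -0.11, mean 0.06, adjusted p = 0.855). At day 1 Saa3 rose by 3.81 ± 0.34 and Cxcl13 by 2.98 ± 0.33 (2.98 and 2.17 with all arrays), and at day 7 Prok2 by 2.36 and Cxcr1 by 1.43 (2.08 and 0.83). The probe sets past the threshold were 71, 252 and 280 at days 1, 3 and 7, of which 67, 150 and 231 had an unadjusted p under 0.05 on the same side with all arrays. With 3 arrays fewer, the spread is shared over 9 arrays. These genes were named after their values were seen.

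Replication-dependent histone genes formed a group of 54, whose median was -0.51, -0.84 and 0.08 at days 1, 3 and 7 against intact. With dap as a block these were -0.51, -0.69 and 0.28. The day 1 median was -0.30 without day 1 replicate 2, and that of day 7 was 0.0058 without day 7 replicate 1, 0.21 without day 7 replicate 3 and 0.049 without intact replicate 1. Between day 3 and day 7 it differed by 0.93, with 51 of 54 higher (camera p = 8.5e-55, or p = 0.0028 with an estimated correlation). The list was put together after histone genes had been seen among the named genes, and these p-values are not adjusted. A labelling batch marked by dap is argued against as the source, since with dap as a block the mean score differed by 0.90 ± 0.17. No biological explanation was tested.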
